A study of Mus musculus with 6 samples.

How the data were processed

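Bulk RNA was sequenced from mouse kidney, 10 mg of frozen tissue per library. Per the labels, RNA was extracted with the Qiagen RNeasy kit and had an RNA integrity number of at least 6, libraries were made with the NEBNext Ultra RNA kit, and the target was 20M paired reads of 150 bp. All 6 libraries carry batch number 1, and each of the 3 groups (WT, G0APOL1, G2APOL1) has 2. The table deposited by the authors holds expected counts per gene, that is estimated numbers of reads, with 1 column per library and no scaling between libraries. Between 1.39% and 1.55% of genes per library have a value that is not whole, with at most 2 decimals. The processing notes list the mouse build mm10 and Cell Ranger ARC 2.0.2 without saying what either was used for; the aligner and the counter are not given in the sources used here. The table has 54146 genes, of which 54079 match GENCODE M21 (GRCm38) by identifier without version, 52480 with version, and 67 do not match. Symbols shared by several identifiers affect 195 genes. The human transgene is not analysed here, and a few list members that the rule for named genes would take are not reported here.

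Expected counts were rounded to whole numbers. Genes with low counts were removed with edgeR's filterByExpr by group, which left 14386 genes. Libraries were scaled with TMM, and normalised read counts are given as edgeR's CPM on that scale. All 6 libraries went into a single fit (edgeR 4.0.16, glmQLFit with robust estimation, R 4.3.3), with 3 residual degrees of freedom, a common biological coefficient of variation of 0.315 and 10.2 prior degrees of freedom. Each comparison was tested with edgeR's quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjusted p values and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Total counts ranged from 8490396 to 11800932. For a gene at 0 counts in a group, the fold is a lower bound against a floor of 3 counts over the group, and for 1 to 3 counts it is given as a 95% exact interval; both cover counting error only.

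Before the data were examined, 42 gene lists (584 genes), the comparisons, the alternatives and the rule for named genes were fixed. Of 35 lists of pathways and cell types, 32 had at least 3 tested members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists within a comparison. Camera with an estimated correlation and fry are given beside it. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. Too few members were tested for the adrenal list (2 members, with Star at -0.44 ± 0.89 in G2APOL1 against WT), the skeletal muscle list (1 member, Pvalb) and the neutrophil list (0 members). The remaining lists, of Y-linked, X-inactivation, sex-biased, immediate early and circadian genes and of the transgene and reporters, describe the samples and were not tested as sets. Named genes are, in each comparison, up to 12 with the largest rise and up to 12 with the largest fall among those that passed, whose groups do not overlap and whose higher group has a mean of at least 1 CPM, without predicted or unnamed gene models. To these come up to 4 members with the smallest p in each list described, and a fixed set given whatever the result: Edn1, Nos3, Ren1, Havcr1, Lcn2, Vcam1, Nlrp3, Tmem173, Xist and Ddx3y.

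Genes with a near-identical copy were found by aligning all transcripts to each other with minimap2 2.31, counting matches of at least 95% identity over at least 50% of the length. Overlaps of exons with other genes were computed from the annotation. The overlap of calls against WT was set beside the number that independent calls give and beside 40 simulations in which unchanged groups were compared with shared WT libraries. The whole procedure was tested on simulated data with 200 of 14386 genes changed, 100 of them 2-fold and 100 of them 4-fold. At 2-fold and 4-fold it recovered 26% and 65% in G2APOL1 against WT, 23% and 62% in G2APOL1 against G0APOL1, and 15% and 59% in G0APOL1 against WT, with 10 false calls of 101, 5 of 90 and 6 of 80. Of 10 simulated lists changed 2-fold, camera called 10 with the preset correlation and 6 with an estimated one, and it called 0 of 20 unchanged lists. The simulated genes were drawn independently and the lists at random. This does not test the preset correlation on lists whose genes move together. Alternatives were another scaling (DESeq2 size factors), other low-count filters, DESeq2 1.42.0, limma-voom, fits of the 4 libraries compared, a replicate block, leaving out mitochondrial genes and leaving out each library. Leaving out genes with a near-identical copy, and giving each comparison with WT a WT library of its own in a fit where the WT libraries are separate groups, were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.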

Results

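Bulk RNA sequencing was measured in 6 mouse kidney libraries, which fall into 3 groups of 2. All mice had a kidney removed at 6 weeks of age and were then fed a diet with 4% salt. The WT group carried no transgene. The G0APOL1 and G2APOL1 groups carried an inducible, cell-specific transgene of human APOL1, the gene of apolipoprotein L1, in its reference form (G0) or in a form linked to risk of kidney disease (G2). The labels put the prefix EC before both transgenic genotypes and do not spell it out. Nothing states that the 2 libraries of a group came from separate animals, so the errors and p values given here measure the spread between these samples. That spread is pooled over all 3 groups and moderated across genes, and is not that of the 2 groups compared alone. Total counts per library were 9639008 and 8752035 in WT, 10027178 and 8490396 in G0APOL1, and 11800932 and 9443888 in G2APOL1. Between 15894 and 16527 genes had at least 1 count. Transcripts of the mitochondrial genome took 14.6% and 21.1% of the counts in WT, 15.5% and 15.9% in G0APOL1, and 12.6% and 14.3% in G2APOL1. Haemoglobin transcripts took 0.224% and 0.164% in WT, 0.0912% and 0.103% in G0APOL1, and 0.0882% and 0.0633% in G2APOL1. On the first principal component, with 38.5% of the variance, the WT libraries lay at -60.16 and -81.28 and the 4 transgenic libraries between 29.72 and 39.37. On the second, with 22.6%, G0APOL1 replicate 2 stood apart at -72.06. On the third, with 16.3%, the WT libraries lay at 55.49 and -45.01 and the 4 transgenic libraries between -19.09 and 27.43. The WT pair was the least alike, with a correlation of log2 CPM of 0.913, against 0.929 in G0APOL1 and 0.958 in G2APOL1.

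The first comparison, G2APOL1 against WT, asks what the risk-variant transgene changes in the kidney under surgery and salt. In G2APOL1, 14 of 18 proximal tubule markers, 8 of 23 genes of fatty acid oxidation and 5 of 20 of cholesterol synthesis rose, while 14 of 29 matrix, 7 of 19 tubular injury, 9 of 26 interferon response, 8 of 16 endothelial, 6 of 16 macrophage and 4 of 8 urothelium genes fell. Each of these lists passed with camera and lost its call with an estimated correlation (adjusted p = 0.165 to 0.600 with an estimated correlation). Gatm, an enzyme of creatine synthesis in the proximal tubule, rose by 2.66 ± 0.21 (log2 fold change ± SE, n = 2 libraries per group, as for all changes below; adjusted p = 1.72e-05), from 25.1 ± 5.8 to 159 ± 14.4 CPM (the normalised read count, mean ± SD). Tnc, the matrix protein tenascin C, fell by 3.93 ± 0.51 (adjusted p = 0.000766), from 34.1 ± 3.95 to 2.28 ± 1.77 CPM, and by 3.24 without G2APOL1 replicate 1 (adjusted p = 0.00183). Of 14386 tested genes, 1178 passed in edgeR's quasi-likelihood test, 657 higher and 521 lower, and 3247 had an unadjusted p under 0.05. Of 32 lists, 15 passed with camera, 4 up and 11 down, 8 with fry and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05.

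Of 18 proximal tubule markers, 14 rose and 4 did not pass, with a median log2 fold change of 1.18 (camera adjusted p = 3.9e-09; adjusted p = 0.165 with an estimated correlation); 15 passed when adjusted over the list alone. The organic anion transporter Slc22a8 rose by 1.30 ± 0.21 (adjusted p = 0.00264), the endocytic receptor Lrp2 by 1.30 ± 0.21 (adjusted p = 0.00277) and the amino acid transporter Slc7a8 by 1.63 ± 0.28 (adjusted p = 0.00383). Fatty acid oxidation had 8 of 23 genes higher and 15 not passing, with a median of 0.43 (camera adjusted p = 0.0022; adjusted p = 0.365 with an estimated correlation); adjusted over the list alone, 10 were higher and 1 lower. They included the carnitine transporters Slc22a5 at 1.02 ± 0.18 and Slc25a20 at 1.06 ± 0.21, and the dehydrogenases Hadh at 1.28 ± 0.27 and Acads at 1.06 ± 0.23. Cholesterol synthesis had 5 of 20 genes higher, 5 also when adjusted over the list alone, with a median of 0.40 (camera adjusted p = 0.00648; adjusted p = 0.600 with an estimated correlation). Among them, Nsdhl rose by 0.94 ± 0.18 and Sc5d by 1.71 ± 0.35. Of 7 distal convoluted tubule markers, 2 rose, Tmem52b by 1.98 ± 0.33 and the calcium-binding protein Calb1 by 0.80 ± 0.20, and 4 passed when adjusted over the list alone. Their median was 0.85 (camera adjusted p = 0.00939; adjusted p = 0.481 with an estimated correlation), and the call was lost without WT replicate 1 (adjusted p = 0.0667). Among the genes named here, Slc22a5, Slc25a20, Acads, Nsdhl and Calb1 lost their call without G2APOL1 replicate 1, the last 3 also without G2APOL1 replicate 2, while the others kept it whichever library was left out.

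Of 29 fibrosis and matrix genes, 14 fell and 15 did not pass, with a median of -1.31 (camera adjusted p = 5.57e-09; adjusted p = 0.451 with an estimated correlation); 21 passed when adjusted over the list alone. Besides Tnc, Pdgfra, a receptor of fibroblasts, fell by 1.31 ± 0.27, the basement membrane collagen Col4a1 by 1.14 ± 0.24 and Sparc by 1.03 ± 0.22. Of 26 interferon response genes, 9 fell, 13 when adjusted over the list alone, with a median of -1.53 (camera adjusted p = 6.82e-07; adjusted p = 0.292 with an estimated correlation). Ifit3, with 1 near-identical copy, fell by 1.86 ± 0.32 (a log2 ratio of -1.80 with the copy summed), Xaf1 by 2.68 ± 0.58, the transcription factor Irf7 by 1.85 ± 0.41 and Ifi44 by 1.53 ± 0.38. Of 19 tubular injury genes, 7 fell, 9 when adjusted over the list alone, with a median of -1.38 (camera adjusted p = 8.49e-07; adjusted p = 0.165 with an estimated correlation). The keratin Krt18 fell by 2.21 ± 0.26 (adjusted p = 0.000467), Anxa2 by 1.65 ± 0.23 (adjusted p = 0.00107), Lcn2, a secreted marker of tubular damage, by 2.77 ± 0.61 (adjusted p = 0.0162) and the adhesion molecule Vcam1 by 2.13 ± 0.52 (adjusted p = 0.025). NF-kB and cytokine genes had a median of -0.91 (camera adjusted p = 0.00090; adjusted p = 0.381 with an estimated correlation), but Nfkbia alone of 14 fell, from 43.0 ± 2.60 to 15.2 ± 0.533 CPM (adjusted p = 0.00392), and it was also the only gene passing when adjusted over the list alone. Of the genes named here, Tnc, Krt18, Anxa2 and Nfkbia kept their call whichever library was left out, and the others lost it without 1 or both of the G2APOL1 libraries. Irf7, Vcam1, Lcn2, Sparc and Xaf1 also lost it without WT replicate 2, where Irf7 was at -1.19 and Vcam1 at -1.43 (adjusted p = 0.167 for both), and Ifi44 without WT replicate 1.

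Markers of other cell types moved with these groups. Of 8 urothelium markers, 4 fell, 8 when adjusted over the list alone, with a median of -2.73 (camera adjusted p = 1.16e-05; adjusted p = 0.298 with an estimated correlation). Among them the uroplakins Upk3a fell by 2.85 ± 0.53, Upk2 by 2.51 ± 0.51 and Upk1b by 2.61 ± 0.55. Of 16 endothelial markers, 8 fell, 10 when adjusted over the list alone, with a median of -0.89 (camera adjusted p = 3.3e-05; adjusted p = 0.381 with an estimated correlation). The sialomucin Emcn fell by 1.44 ± 0.20, Plvap by 1.16 ± 0.18, Esam by 1.17 ± 0.22 and Tie1 by 1.16 ± 0.26. Of 10 endothelial activation genes, 3 fell: Angpt2 fell by 2.65 ± 0.32, Vcan fell by 4.51 ± 1.20 and Vcam1 fell as given above. Their median was -1.34 (camera adjusted p = 0.000188; adjusted p = 0.381 with an estimated correlation), and 5 passed when adjusted over the list alone. Of 16 macrophage and monocyte markers, 6 fell, 6 also when adjusted over the list alone, with a median of -1.28 (camera adjusted p = 0.000808; adjusted p = 0.478 with an estimated correlation), a call lost without WT replicate 2 (adjusted p = 0.101). Lyz2, with 1 near-identical copy, fell by 1.90 ± 0.26 (-1.87 with the copy summed), C1qa by 1.92 ± 0.35 and Cd14 by 1.74 ± 0.43. Upk3a, Emcn, Angpt2, Lyz2 and C1qa kept their call whichever library was left out, Upk3a at -2.25 without WT replicate 1 (adjusted p = 0.0231). The other genes named here lost it without G2APOL1 replicate 1, where Upk1b was at -1.99 (adjusted p = 0.144) and Vcan at -3.43 (adjusted p = 0.167); Upk2 and Vcan also lost it without WT replicate 2, and Vcan and Cd14 without WT replicate 1.

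Of 11 smooth muscle and mesangial markers, 4 fell, 6 when adjusted over the list alone, with a median of -0.82 (camera adjusted p = 0.00249; adjusted p = 0.439 with an estimated correlation). Itga8 fell by 1.73 ± 0.38, Rgs5 by 0.97 ± 0.24, Acta2 by 0.82 ± 0.21 and Tagln, which shares 62.4% of its exonic bases with a gene on the opposite strand, by 0.75 ± 0.20. Of 9 principal cell markers, 3 fell, 4 when adjusted over the list alone, with a median of -0.64 (camera adjusted p = 0.0276; adjusted p = 0.481 with an estimated correlation). The water channel Aqp2 fell by 1.58 ± 0.28, Fxyd4 by 1.41 ± 0.30 and Aqp4 by 0.78 ± 0.19; the list call was lost without WT replicate 2 (adjusted p = 0.0628) or G2APOL1 replicate 2 (adjusted p = 0.101). Of 6 red cell markers, 4 fell, 5 when adjusted over the list alone, with a median of -1.17 (camera adjusted p = 0.00641; adjusted p = 0.439 with an estimated correlation), a call lost without WT replicate 1 (adjusted p = 0.129). The haemoglobin genes Hba-a1 and Hbb-bt fell by 2.32 ± 0.21 and 1.19 ± 0.24. Each has 1 near-identical copy, and with the copy summed the log2 ratios were -1.44 for Hba-a1, at 481 against 1305 CPM, and -0.96 for Hbb-bt. Of the genes named here only Hba-a1 kept its call whichever library was left out, and the others lost it without 1 or both of the G2APOL1 libraries, with adjusted p up to 0.468 for Acta2.

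The lists of the glomerulus, of blood pressure and of several stress responses did not pass in G2APOL1 against WT. None of 14 podocyte markers passed in edgeR's quasi-likelihood test, also when adjusted over the list alone, 2 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 each (median -0.33, camera adjusted p = 0.253). Among 13 genes of the renin-angiotensin-aldosterone system, Sgk1, a salt- and steroid-responsive kinase, fell by 1.93 ± 0.29 (adjusted p = 0.00298), while 2 genes rose when adjusted over the list alone (median -0.03, camera adjusted p = 0.964). Ren1, the renin gene, was at -1.65 ± 0.55 (adjusted p = 0.152) and ranged in WT from 51.3 to 160 CPM. Of 24 sodium transport genes, 2 rose and 2 fell: Slc26a4 rose by 1.85 ± 0.26 and the proximal phosphate carrier Slc34a1 by 1.19 ± 0.22, while the kinase Stk39 fell by 0.92 ± 0.22 (3 higher and 3 lower when adjusted over the list alone, median 0.20, camera adjusted p = 0.238). Of 16 vasoactive genes, Ptgs1 alone fell, by 1.41 ± 0.26 (median -0.63, camera adjusted p = 0.0818). The endothelial nitric oxide synthase Nos3 was at -1.01 ± 0.43 (adjusted p = 0.184) and endothelin 1, Edn1, at -1.29 ± 1.14 (adjusted p = 0.563). Of 14 inflammasome, STING and lytic death genes, Casp4 fell by 4.42 ± 1.09 (median -0.49, camera adjusted p = 0.116). Tmem173, the gene of STING, was at -0.69 ± 0.99 (adjusted p = 0.738), and the injury marker Havcr1 was at -0.23 ± 1.17 (adjusted p = 0.939) with at most 22 counts in any library. The sodium transport list passed without WT replicate 2 (adjusted p = 0.0457), and the inflammasome list passed, down, without G2APOL1 replicate 1 (adjusted p = 0.0307). Sgk1 and Slc26a4 kept their call whichever library was left out, Sgk1 at -1.30 without WT replicate 1, while Slc34a1, Stk39, Ptgs1 and Casp4 lost it without either G2APOL1 library, and Stk39 and Casp4 without WT replicate 2, with Casp4 at -2.90 there (adjusted p = 0.444).

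Among the other stress and energy lists in G2APOL1 against WT, Nrf2 targets had 4 of 14 genes higher and 1 lower, 6 and 1 when adjusted over the list alone (median 0.40, camera adjusted p = 0.053). Osgin1, induced by oxidative stress, rose by 1.76 ± 0.18 and the glutathione reductase Gsr by 1.15 ± 0.20. Of 26 nuclear genes of the respiratory chain, 3 rose, 4 when adjusted over the list alone, with the succinate dehydrogenase subunits Sdha at 1.69 ± 0.23 and Sdhd at 0.87 ± 0.20 (median 0.19, camera adjusted p = 0.0753). None of 13 genes of the mitochondrial genome passed in edgeR's test, also when adjusted over the list alone, whereas DESeq2 called 4 and limma-voom 3, as many as had an unadjusted p under 0.05 (median -0.29, camera adjusted p = 0.0946). Of 14 hypoxia genes, Ndrg1 rose by 1.19 ± 0.26 (median 0.24, camera adjusted p = 0.326). Of 15 complement and acute phase genes, 1 rose and 6 fell, with the complement inhibitor Serping1 down by 2.52 ± 0.21 and Cp by 1.48 ± 0.24, and Cfb up by 1.00 ± 0.22; the list median was 0.19 and its mean -0.50, with camera's direction down (camera adjusted p = 0.239). In the unfolded protein list Xbp1 rose by 1.11 ± 0.21 and Ddit4 fell by 2.07 ± 0.34 (median 0.01, mean -0.08, camera adjusted p = 0.619). Of 19 genes of mitochondrial dynamics, Opa1 rose by 0.64 ± 0.18 and Fis1 fell by 0.69 ± 0.18 (median 0.10, mean -0.02, camera adjusted p = 0.651). Mcm6 was the only one of 19 proliferation genes to rise (median 0.09, mean -0.20, camera adjusted p = 0.951). Of 9 thick limb markers, Ppp1r1a fell by 0.76 ± 0.18 (median -0.16, camera adjusted p = 0.704), and of 9 intercalated cell markers Slc26a4 rose while Slc4a1 fell by 1.15 ± 0.27 and Aqp6 by 1.46 ± 0.37 (median -0.21, camera adjusted p = 0.951, with fry's direction up). None of 11 lymphocyte markers passed in edgeR's test, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 (median -0.55, camera adjusted p = 0.381). None of 9 adipocyte markers passed in edgeR's test, against 1 each with DESeq2, limma-voom and an unadjusted p under 0.05 (median 0.62, camera's direction down, camera adjusted p = 0.704). The direction of this list depended on the library left out. It was down without G2APOL1 replicate 2 (adjusted p = 0.00824) and up without G2APOL1 replicate 1 (adjusted p = 0.0687) or WT replicate 1 (adjusted p = 0.871). Other lists passed in the direction given when a library was left out. These were Nrf2 targets without G0APOL1 replicate 1 (adjusted p = 0.0347), G0APOL1 replicate 2 (adjusted p = 0.0377) or G2APOL1 replicate 2 (adjusted p = 0.0449), and nuclear respiratory chain genes without WT replicate 1 (adjusted p = 0.00162) or G2APOL1 replicate 2 (adjusted p = 0.0226). Without WT replicate 1 the mitochondrial genome (adjusted p = 0.00451) and lymphocyte markers (adjusted p = 0.0369) passed, down, as did complement without G2APOL1 replicate 2 (adjusted p = 0.0402). Osgin1, Gsr, Sdha, Serping1, Ddit4, Mcm6 and Slc26a4 kept their call whichever library was left out. The other genes given here as changed lost it without 1 or both of the G2APOL1 libraries, and Aqp6 was at -0.66 without WT replicate 2 (adjusted p = 0.0881).

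Among the genes with the largest rises in G2APOL1, Azgp1 (ENSMUSG00000037053.6, chromosome 5, 137981520 to 137990233, GRCm38) rose by 8.08 ± 0.52, from 0.446 ± 0.631 to 129.79 ± 9.82 CPM. Dpys, the pyrimidine-degrading dihydropyrimidinase (ENSMUSG00000022304.13, chromosome 15, 39768487 to 39857470), had 0 counts in WT and was at least 36.8-fold higher. Ces2h was at least 18.9-fold, Kdm8 16.4-fold and Tspyl5 14.9-fold higher, each against 0 counts in WT. Ugt1a9 was at least 93.7-fold higher, but shares 59.9% of its exonic bases with other genes of the Ugt1a cluster. Camk2b and Fign rose from 1 and 2 counts over the WT group, with counting intervals for the ratio of 10.3 to 2378 and 8.01 to 254. Hmx2 rose by 4.38 ± 0.90, the potassium channel Kcnj2 by 4.19 ± 0.96 and the replication helicase Mcm6 by 4.00 ± 0.67. Serpina1d, an alpha-1 antitrypsin gene with 4 near-identical copies, rose by 7.54 ± 0.37, and by less with the copies summed, at 243 against 17.6 CPM (log2 ratio 3.78). Tpbgl was at least 69.8-fold lower, with 0 counts in G2APOL1, as was Oit1 at least 55.2-fold, the mitotic kinesin Kif23 30.7-fold, Nxpe5 27.0-fold, Wnt10a 26.7-fold, the estrogen receptor Esr2 21.9-fold, Lst1 20.1-fold and Zfp951 19.0-fold. Hist1h2bq, with 1 near-identical copy, was at least 65.0-fold lower, and with the copy summed stood at 0 against 12.7 CPM. Atp12a and Adgrf1 fell to 1 count over the G2APOL1 group each, with ratio intervals of 44.0 to 9825 and 17.7 to 4025. Rps3a3, a processed pseudogene with 5 near-identical copies, fell by 7.19 ± 0.37, while the family summed over its copies stood at 470 against 502 CPM.

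Of these 24 genes, 9 kept their call whichever library was left out: Azgp1, Dpys, Ugt1a9, Mcm6, Serpina1d, Tpbgl, Oit1, Hist1h2bq and Rps3a3. Hmx2 was at 3.61 and Azgp1 at 7.18 without WT replicate 2, and Kcnj2 at 3.17 without WT replicate 1. Among others, the log2 fold change without WT replicate 1 went from -8.2 to -7.0 for Wnt10a and from -7.7 to -6.7 for Zfp951. For Atp12a it went from -7.6 to -6.1 without WT replicate 2, and for Adgrf1 from -6.2 to -5.3 without G2APOL1 replicate 1. The number of genes called for G2APOL1 against WT was 1835 without WT replicate 1, 338 without G2APOL1 replicate 1 and 366 without G2APOL1 replicate 2. Without the filter on low counts it was 1806.

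**Figure D1:**
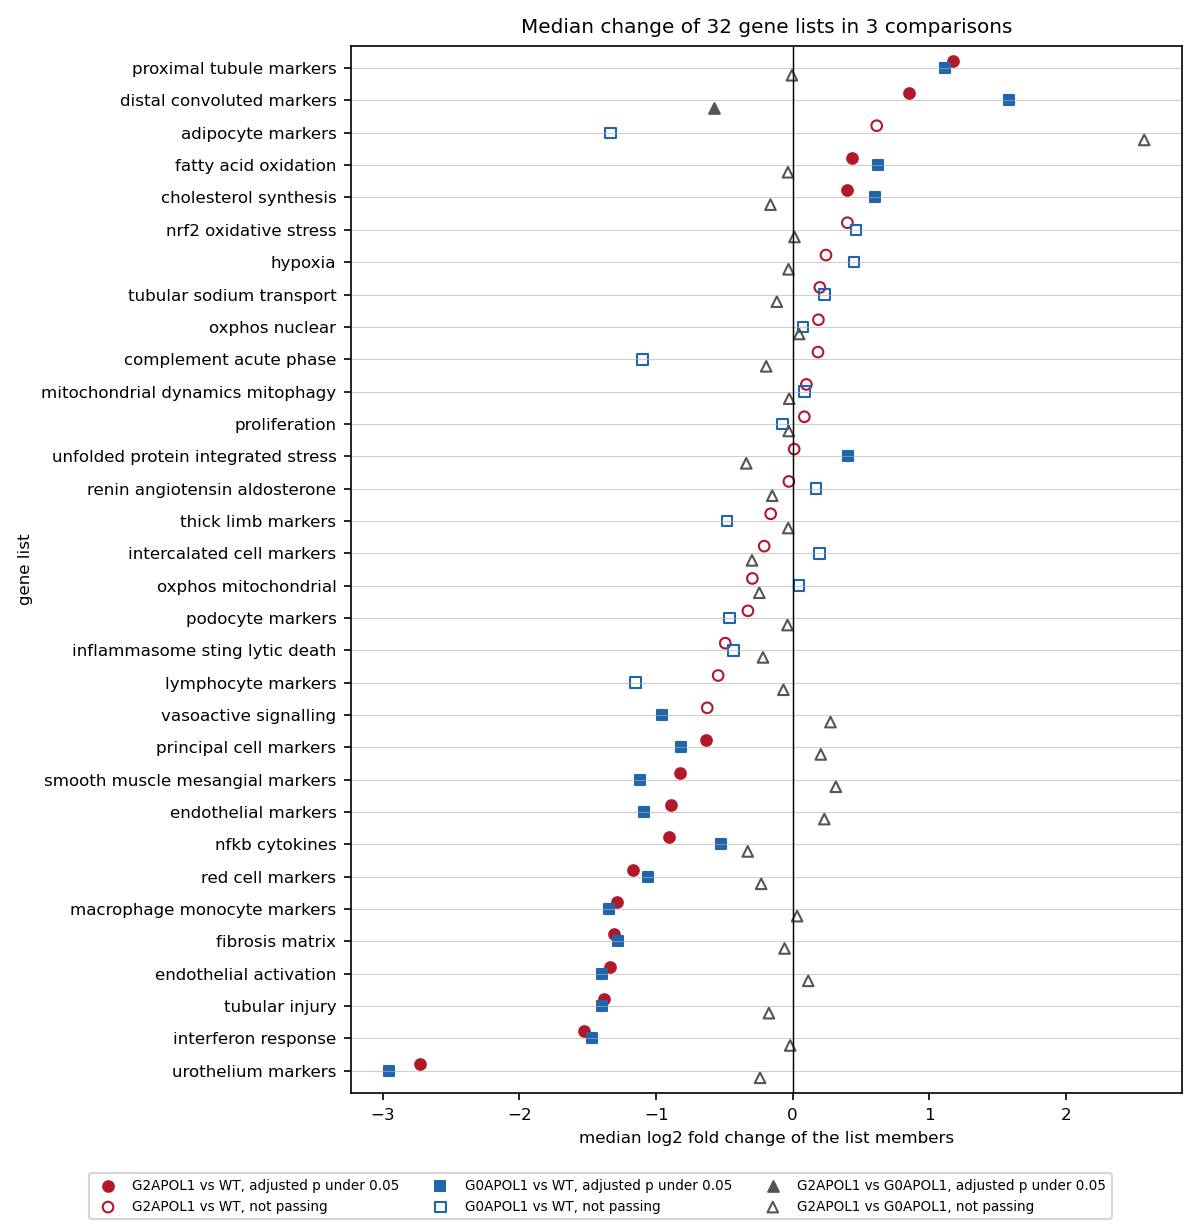
Median log2 fold change of the members of 32 gene lists (horizontal axis) for each list (vertical axis) in the 3 comparisons, with 2 libraries per group; filled symbols mark a camera adjusted p under 0.05 and open symbols lists that did not pass. Against WT the proximal tubule list lies at 1.18 in G2APOL1 and 1.11 in G0APOL1 and the urothelium list at -2.73 and -2.96, while between the transgenic groups the distal convoluted tubule list alone is filled (-0.58).

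G0APOL1 against WT asks what the reference-variant transgene changes. In G0APOL1, 14 of 18 proximal tubule and 4 of 7 distal convoluted tubule markers rose, while 12 of 29 matrix, 5 of 8 urothelium, 9 of 16 endothelial and 5 of 16 macrophage genes fell, and of 19 tubular injury genes 6 fell and 1 rose. Each of these lists passed with camera and lost its call with an estimated correlation (adjusted p = 0.209 to 0.327 with an estimated correlation). Gatm rose by 2.66 ± 0.21 (adjusted p = 2.37e-05), to 158 ± 4.63 CPM, and Calb1 by 1.78 ± 0.20 (adjusted p = 0.000242), from 142 ± 21.5 to 488 ± 25.2 CPM. Tnc fell by 4.19 ± 0.52 (adjusted p = 0.000458) and Emcn by 1.73 ± 0.20 (adjusted p = 0.000335). In all, 1175 of 14386 tested genes passed, 645 higher and 530 lower, and 3242 had an unadjusted p under 0.05. Of 32 lists, 17 passed with camera, 5 up and 12 down, 14 with fry and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05.

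The median of the proximal tubule markers was 1.11 (camera adjusted p = 1.8e-09; adjusted p = 0.209 with an estimated correlation), and 15 of 18 passed when adjusted over the list alone. Slc22a8 rose by 1.84 ± 0.21, Slc7a8 by 2.07 ± 0.28 and Lrp2 by 1.45 ± 0.21. Fatty acid oxidation had 9 of 23 genes higher; adjusted over the list alone, 12 were higher and 1 lower. Its median was 0.63 (camera adjusted p = 5.4e-05; adjusted p = 0.209 with an estimated correlation), and it included Hadh at 1.32 ± 0.27 and the peroxisomal enzyme Ehhadh at 1.18 ± 0.25. Cholesterol synthesis had 3 of 20 genes higher, among them Nsdhl by 0.66 ± 0.18, and 7 when adjusted over the list alone. Its median was 0.60 (camera adjusted p = 0.00192; adjusted p = 0.459 with an estimated correlation), and the call was lost without G0APOL1 replicate 1 (adjusted p = 0.511). Of 7 distal convoluted tubule markers, 4 rose, 6 when adjusted over the list alone, among them Tmem52b by 2.34 ± 0.34, parvalbumin, Pvalb, by 1.45 ± 0.29 and Klhl3 by 1.55 ± 0.32. Their median was 1.59 (camera adjusted p = 0.000141; adjusted p = 0.327 with an estimated correlation). Of 18 genes of the unfolded protein and integrated stress responses, 4 rose, 6 when adjusted over the list alone, namely the transcription factor Xbp1 by 1.12 ± 0.21 and the chaperones Calr by 0.89 ± 0.22, Hyou1 by 0.86 ± 0.22 and Hsp90b1 by 0.75 ± 0.20. The list median was 0.41 (camera adjusted p = 0.0202; adjusted p = 0.327 with an estimated correlation). That call was lost without WT replicate 2 (adjusted p = 0.233) or G0APOL1 replicate 1 (adjusted p = 0.0834). In G2APOL1 against WT the same list had a median of 0.01 (camera adjusted p = 0.619), with Xbp1 at 1.11 ± 0.21. Of the genes named here, Slc22a8, Slc7a8, Lrp2 and Tmem52b kept their call for G0APOL1 against WT whichever library was left out. Ehhadh, Pvalb, Xbp1, Calr, Hyou1 and Hsp90b1 lost it without G0APOL1 replicate 1, Hadh and Klhl3 without G0APOL1 replicate 2, and Nsdhl without any 1 of the 6 libraries.

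Fibrosis and matrix genes fell in 12 of 29 cases, 23 when adjusted over the list alone, with a median of -1.28 (camera adjusted p = 1.8e-09; adjusted p = 0.327 with an estimated correlation). Sparc fell by 1.43 ± 0.22 and Pdgfra by 1.44 ± 0.27. Of 26 interferon response genes, 6 fell and 1 rose, 12 and 1 when adjusted over the list alone, with a median of -1.47 (camera adjusted p = 1.98e-07; adjusted p = 0.209 with an estimated correlation). Ifit3 fell by 1.83 ± 0.32 (a log2 ratio of -1.87 with its near-identical copy summed), Irf7 by 2.30 ± 0.42 and Ifit2 by 2.36 ± 0.45. Of 19 tubular injury genes, 6 fell and 1 rose, 9 and 1 when adjusted over the list alone, with a median of -1.40 (camera adjusted p = 4.34e-05; adjusted p = 0.209 with an estimated correlation). Krt18 fell by 2.02 ± 0.26, Krt19 by 2.72 ± 0.49 and Vim, the mesenchymal filament protein, by 1.54 ± 0.27. Lcn2 fell by 3.17 ± 0.63 (adjusted p = 0.00917), and Vcam1 was at -1.40 ± 0.50 (adjusted p = 0.116). None of 14 NF-kB and cytokine genes passed in edgeR's test, DESeq2 or limma-voom, also when adjusted over the list alone, and 3 had an unadjusted p under 0.05, although the list passed (median -0.53, camera adjusted p = 0.0222; adjusted p = 0.327 with an estimated correlation). It no longer passed without WT replicate 2 (adjusted p = 0.355), G0APOL1 replicate 1 (adjusted p = 0.0671) or G0APOL1 replicate 2 (adjusted p = 0.0655). Of the genes that fell here only Ifit2 lost its call with a library left out (adjusted p = 0.0502 without G0APOL1 replicate 1), while Irf7 was at -1.65 (adjusted p = 0.0452) without WT replicate 2 and Lcn2 at -2.43 (adjusted p = 0.0379) without G0APOL1 replicate 2.

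Of 8 urothelium markers, 5 fell, 7 when adjusted over the list alone, with a median of -2.96 (camera adjusted p = 3.2e-06; adjusted p = 0.209 with an estimated correlation). Upk2 fell by 4.60 ± 0.59 and Upk3b by 4.28 ± 0.73. Of 16 endothelial markers, 9 fell, 12 when adjusted over the list alone, with a median of -1.09 (camera adjusted p = 2.41e-07; adjusted p = 0.300 with an estimated correlation). Plvap fell by 1.56 ± 0.19 and the endothelial cadherin Cdh5 by 1.77 ± 0.30. Endothelial activation had 4 of 10 genes lower, 6 when adjusted over the list alone, with a median of -1.39 (camera adjusted p = 1.55e-05; adjusted p = 0.300 with an estimated correlation). Angpt2 fell by 3.18 ± 0.33, Icam1 by 1.06 ± 0.28 and Vwf by 2.63 ± 0.74. Of 16 macrophage and monocyte markers, 5 fell, 6 when adjusted over the list alone, with a median of -1.34 (camera adjusted p = 0.000529; adjusted p = 0.327 with an estimated correlation), a call lost without WT replicate 2 (adjusted p = 0.150). C1qa fell by 1.93 ± 0.35 and Cd14 by 2.00 ± 0.44. Smooth muscle and mesangial markers fell in 5 of 11 cases, 8 when adjusted over the list alone, with a median of -1.12 (camera adjusted p = 0.000184; adjusted p = 0.327 with an estimated correlation). Tagln fell by 1.34 ± 0.21 and Itga8 by 2.01 ± 0.38. Of 9 principal cell markers, 4 fell, 5 when adjusted over the list alone, with a median of -0.82 (camera adjusted p = 0.00157; adjusted p = 0.327 with an estimated correlation). Aqp4 fell by 1.90 ± 0.20 and Aqp2 by 1.71 ± 0.28. Without G0APOL1 replicate 2, Vwf was at -1.80 (adjusted p = 0.139) and Icam1 (adjusted p = 0.181), Cd14 (adjusted p = 0.092) and Itga8 (adjusted p = 0.0541) also lost their call; Vwf and Icam1 lost it without WT replicate 2 as well, and Upk3b was at -3.30 (adjusted p = 0.0188) without WT replicate 1.

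Of 6 red cell markers, 3 fell, 5 when adjusted over the list alone, with a median of -1.06 (camera adjusted p = 0.0186; adjusted p = 0.327 with an estimated correlation). Hba-a1 fell by 1.33 ± 0.20 (a log2 ratio of -0.96 with its near-identical copy summed), and the list call was lost without WT replicate 1 (adjusted p = 0.272) or G0APOL1 replicate 1 (adjusted p = 0.0807). Of 16 vasoactive genes, Ptgs1 fell by 1.60 ± 0.26 and the endothelin receptor Ednrb by 1.88 ± 0.35, and 5 passed when adjusted over the list alone. The list median was -0.95 (camera adjusted p = 0.00916; adjusted p = 0.300 with an estimated correlation), and the call was lost without WT replicate 2 (adjusted p = 0.0882) or G0APOL1 replicate 2 (adjusted p = 0.0598). Nos3 was at -1.54 ± 0.45 (adjusted p = 0.0513) and Edn1 at -3.76 ± 1.32 (adjusted p = 0.105). None of 14 podocyte markers passed in edgeR's test, DESeq2 or limma-voom, also when adjusted over the list alone, and 3 had an unadjusted p under 0.05 (median -0.46, camera adjusted p = 0.0851). In the renin-angiotensin-aldosterone list of 13, the peptidase Mme alone rose, by 0.90 ± 0.22 (median 0.17, camera adjusted p = 0.169), and Ren1 was at -1.07 ± 0.54 (adjusted p = 0.326). Of 24 sodium transport genes, 5 rose and 2 fell, 8 and 3 when adjusted over the list alone (median 0.23, camera adjusted p = 0.0614), with Kcnj16 up by 1.28 ± 0.20. Havcr1 was at 0.65 ± 1.16 (adjusted p = 0.818) and Tmem173 at -0.29 ± 0.98 (adjusted p = 0.917), and none of the 14 inflammasome, STING and lytic death genes passed in edgeR's test, also when adjusted over the list alone. DESeq2 called 2 of them and limma-voom 0, and 3 had an unadjusted p under 0.05 (median -0.43, camera adjusted p = 0.0727). Without WT replicate 1 the podocyte (adjusted p = 0.0133) and inflammasome (adjusted p = 0.0368) lists passed, down, and the sodium transport list passed, up, without WT replicate 2 (adjusted p = 0.0134) or G0APOL1 replicate 2 (adjusted p = 0.0421). Ednrb lost its call without G0APOL1 replicate 2 (adjusted p = 0.0567), and Mme without WT replicate 1 or either G0APOL1 library (adjusted p up to 0.158).

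Nrf2 targets in G0APOL1 had 4 of 14 genes higher and 1 lower, 6 and 2 when adjusted over the list alone, with Osgin1 up by 1.08 ± 0.18 and the haem oxygenase Hmox1 by 1.02 ± 0.28 (median 0.46, camera adjusted p = 0.0602). Of 26 nuclear genes of the respiratory chain, 3 rose, 4 when adjusted over the list alone, with Sdha at 1.38 ± 0.23 and Ndufs1 at 0.82 ± 0.20 (median 0.08, camera adjusted p = 0.147). None of 13 genes of the mitochondrial genome passed in edgeR's test or limma-voom, 1 had an unadjusted p under 0.05 and DESeq2 called 2 (median 0.05, camera's direction down, camera adjusted p = 0.869). Of 14 hypoxia genes, Ndrg1 rose by 2.05 ± 0.26, and 2 rose when adjusted over the list alone (median 0.45, camera adjusted p = 0.169). Of 15 complement and acute phase genes, 1 rose and 4 fell, 2 and 7 when adjusted over the list alone, with Serping1 down by 1.89 ± 0.20 and complement C3 by 3.03 ± 0.66 (median -1.10, camera adjusted p = 0.143). Of 9 thick limb markers, Egf rose by 1.61 ± 0.19, and Ppp1r1a fell by 0.67 ± 0.18 and Cldn19 by 0.98 ± 0.27 (median -0.48, camera adjusted p = 0.779). Of 9 intercalated cell markers, Slc26a4, the exchanger pendrin, rose by 2.18 ± 0.26 and Slc4a1 fell by 1.15 ± 0.27 (median 0.20, camera adjusted p = 0.495). Of 19 genes of mitochondrial dynamics, Fis1 fell by 0.80 ± 0.18 (median 0.09, camera adjusted p = 0.633). None of 19 proliferation genes passed in edgeR's test, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 (median -0.07, camera's direction up, camera adjusted p = 0.779). None of 11 lymphocyte markers passed in edgeR's test or limma-voom, while 1 had an unadjusted p under 0.05 and DESeq2 called 1 (median -1.15, camera adjusted p = 0.182). Of 9 adipocyte markers, the fatty acid binding protein Fabp4 fell by 2.20 ± 0.41 (median -1.33, camera adjusted p = 0.0769), and the list passed, down, without WT replicate 2 (adjusted p = 0.0373), G2APOL1 replicate 1 (adjusted p = 0.0360) or G2APOL1 replicate 2 (adjusted p = 0.0359). Also when a library was left out, Nrf2 targets passed, up, without G0APOL1 replicate 2 (adjusted p = 0.0247), nuclear respiratory chain genes, up, without WT replicate 1 (adjusted p = 0.00304) or G0APOL1 replicate 2 (adjusted p = 0.0285), intercalated cell markers, up, without WT replicate 2 (adjusted p = 0.0357), and lymphocyte markers, down, without WT replicate 1 (adjusted p = 0.0132). Osgin1, Sdha, Ndrg1, Serping1, Egf and Slc26a4 kept their call whichever library was left out, and the other genes given here as changed lost it without G0APOL1 replicate 1 (C3 was at -2.09 without WT replicate 2, adjusted p = 0.0641).

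The largest rises in G0APOL1 included Azgp1 by 8.05 ± 0.52, Dpys at least 119-fold, Ces2h at least 15.8-fold, Kdm8 at least 13.3-fold and Ugt1a9, with its shared exons, at least 240-fold against 0 counts in WT. Reep3 (ENSMUSG00000019873.8, chromosome 10, 67009189 to 67096945), which encodes a protein of the endoplasmic reticulum, had 3 counts over the WT group and 1349 over G0APOL1, a ratio with a counting interval of 165 to 2350. Pstpip2 was at least 23.7-fold higher. Kcnj2 rose by 6.22 ± 0.95, Cpn1 by 4.54 ± 0.91, Nepn by 4.04 ± 1.02, the liver-type glycogen synthase Gys2 by 3.71 ± 0.65 and Emx2os, antisense to Emx2, by 3.74 ± 0.87. Among genes with 0 counts in G0APOL1, the matrix proteoglycan Vcan was at least 50.2-fold lower, the retinol-binding protein Rbp7 42.1-fold, Tmem238l 31.9-fold, Tubg2 25.1-fold, AA467197 and Nxpe5 22.9-fold each, Aox3 22.6-fold, Gpx7 21.1-fold, and Irak3 and Tex21 19.5-fold each. Hist1h2bq was at least 55.1-fold lower, and Hist1h2al, a processed pseudogene with 6 near-identical copies, at least 38.1-fold, but with the copies summed Hist1h2bq stood at 10.4 against 12.7 CPM and Hist1h2al at 354 in both groups.

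Of these 24 genes, 10 kept their call whichever library was left out: Azgp1, Dpys, Ugt1a9, Reep3, Kcnj2, Gys2, Vcan, Rbp7, Hist1h2bq and Hist1h2al. Azgp1 was at 7.14 without WT replicate 2, Kcnj2 at 4.99 without G0APOL1 replicate 2, and Cpn1 at 3.52 and Nepn at 3.03 without WT replicate 1. Among others, the log2 fold change without WT replicate 1 went from -8.7 to -7.1 for Tmem238l and from -8.3 to -7.5 for Tubg2. For Irak3 it went from -8.0 to -6.9 without WT replicate 2. The number of genes called for G0APOL1 against WT was 599 without G0APOL1 replicate 1 and 663 without G0APOL1 replicate 2. In a fit of the 4 libraries of these groups alone it was 658.

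The changes of the transgenic groups against WT overlapped. In total 736 genes were called in both comparisons in the same direction, 430 higher and 306 lower, and 3 in opposite directions. Independent calls would give 29.5 and 19.2. In 40 simulations of unchanged groups set against shared WT libraries, the mean was 0.225 and 0.05 genes and the highest 4. Those draws gave a mean of only 1.125 calls in G2APOL1 against WT, so little could overlap. They do not show how many shared calls real changes would give through common WT libraries. Across genes, which are not independent replicates, the log2 fold changes of the comparisons correlated at 0.728, against 0.50 in the simulations, and their covariance was 0.657, against 0.165. Slc34a1, for example, was at 1757.6 ± 258 CPM in WT, 3923.7 ± 35.5 in G0APOL1 and 4003.4 ± 103 in G2APOL1. The overlap was 1231 genes without WT replicate 1, 404 without G0APOL1 replicate 1, 248 without G2APOL1 replicate 1 and 277 without G2APOL1 replicate 2. Both comparisons use the same 2 WT libraries. In the fit that separates them, each WT library stands alone, so the spread comes from the transgenic pairs only. The spread of the WT pair, the least alike, is then left out of the errors, and the overlap counts can be too high. With a WT library of its own for each comparison, chosen after seeing the data, the overlap was 510 genes (310 higher and 200 lower, 32.5 and 14.9 for independent calls, 13 opposite) with WT replicate 1 for G2APOL1 and WT replicate 2 for G0APOL1, and 493 (294 and 199, 38.8 and 20.5 for independent calls, 14 opposite) the other way round. The correlations of the fitted log2 fold changes were then 0.281 and 0.202, and their covariances 0.6345 and 0.4861. The 0.728 and 0.657 above came from log2 CPM with a prior count of 2, so these values cannot be set beside them.

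**Figure D2:**
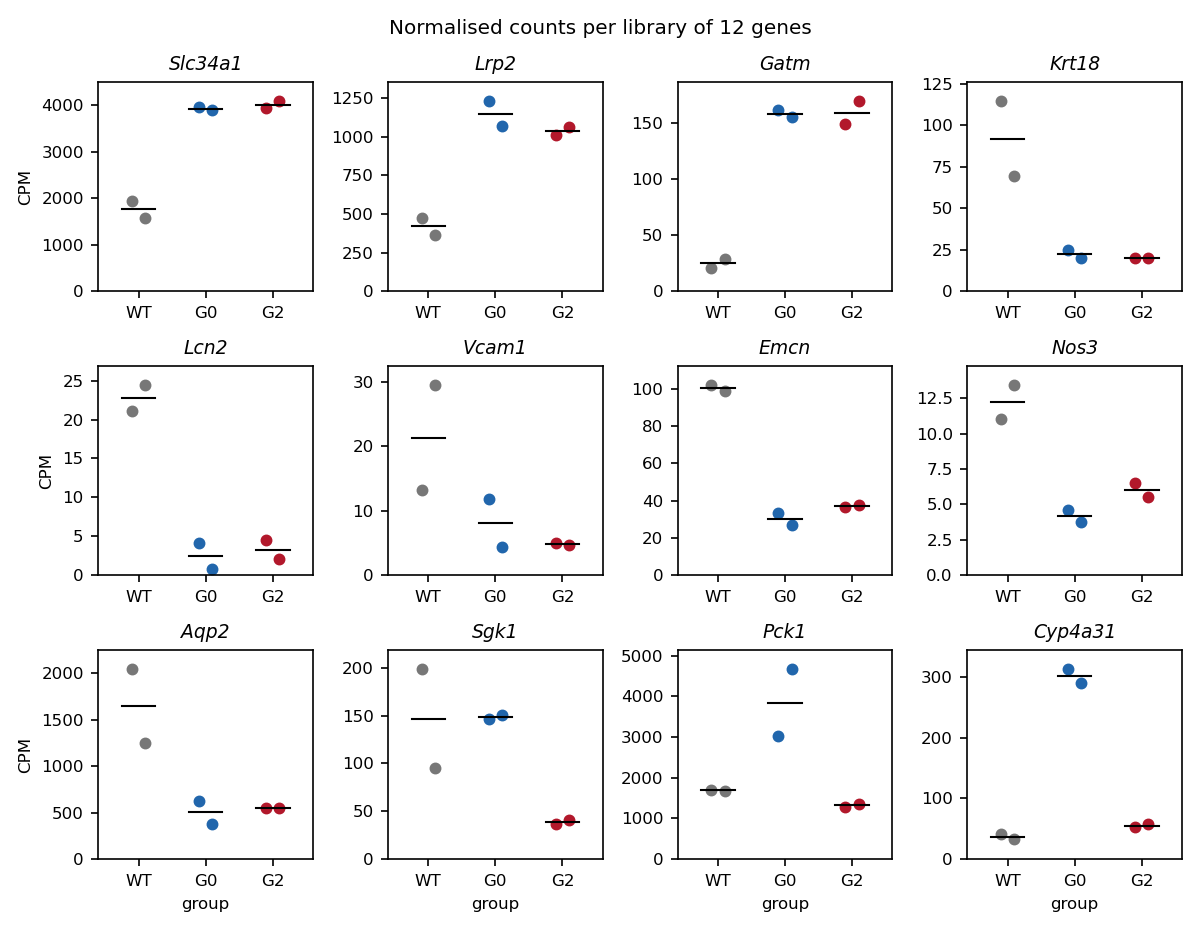
Normalised read counts (CPM, vertical axes from 0) of 12 genes in each of the 6 libraries by group (WT, G0APOL1 as G0, G2APOL1 as G2), with points for libraries and lines for the means of 2. Slc34a1, Lrp2 and Gatm were lower, and Krt18, Lcn2 and Emcn higher, in both WT libraries than in all transgenic libraries, whereas Sgk1, at 38.6 ± 2.88 CPM in G2APOL1, was lower than in both other groups.

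G2APOL1 against G0APOL1 sets the risk variant against the reference variant of the same transgene. Sgk1 (ENSMUSG00000019970.15, chromosome 10, 21882184 to 21999903) fell by 1.94 ± 0.29 (adjusted p = 0.0155), from 148 ± 3.03 to 38.6 ± 2.88 CPM. The stress-induced inhibitor of mTOR signalling Ddit4 fell by 1.93 ± 0.34 (adjusted p = 0.0254), the transcriptional repressor Bcl6 by 2.42 ± 0.41 (adjusted p = 0.0245), from 38.6 ± 24.4 to 7.17 ± 1.38 CPM, and Pck1, an enzyme of gluconeogenesis, by 1.54 ± 0.24 (adjusted p = 0.0138). The clock repressor Nr1d1 rose by 1.62 ± 0.21 (adjusted p = 0.0031), from 13.9 ± 0.851 to 43.0 ± 0.268 CPM, and shares 8.55% of its exonic bases with Thra. In the fit of all 6 libraries 69 genes passed, 25 higher and 44 lower, with 970 at an unadjusted p under 0.05. In a fit of the 4 transgenic libraries alone 119 passed. Of the 69, 18 (26.1%) have a near-identical copy elsewhere among the transcripts, against 3.93% of all tested genes. Sgk1 lost its call without G0APOL1 replicate 1 (adjusted p = 0.0644), G0APOL1 replicate 2 (adjusted p = 0.0961) or G2APOL1 replicate 1 (adjusted p = 0.0698), Ddit4 without G0APOL1 replicate 2 (adjusted p = 0.258) or G2APOL1 replicate 2 (adjusted p = 0.163), Bcl6 without WT replicate 1 (adjusted p = 0.0858), WT replicate 2 (adjusted p = 0.0523), G0APOL1 replicate 2 (adjusted p = 0.14) or G2APOL1 replicate 2 (adjusted p = 0.14), and Pck1 without G0APOL1 replicate 2 (adjusted p = 0.155), G2APOL1 replicate 1 (adjusted p = 0.292) or G2APOL1 replicate 2 (adjusted p = 0.223). Without G0APOL1 replicate 2 the log2 fold change was -1.57 for Bcl6, -1.36 for Ddit4, -1.19 for Pck1 and -1.92 for Sgk1.

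Of 32 lists, the distal convoluted tubule markers alone passed with camera, 0 passed with fry and 0 with an estimated correlation (1 and 0 at an unadjusted p under 0.05). The markers had a median of -0.58 (camera adjusted p = 0.0272; adjusted p = 0.918 with an estimated correlation). Calb1 was the only one of its 7 members to fall, by 0.98 ± 0.20 (adjusted p = 0.0455), and the only one when adjusted over the list alone. The list call was lost without G0APOL1 replicate 2 (adjusted p = 0.143), G2APOL1 replicate 1 (adjusted p = 0.0851) or G2APOL1 replicate 2 (adjusted p = 0.158). In the renin-angiotensin-aldosterone list, Sgk1 and Mme fell, Mme by 1.23 ± 0.22, and 3 of 13 passed when adjusted over the list alone (median -0.15, camera adjusted p = 0.152). Egf, made in the thick limb and distal tubule, was the only one of 9 thick limb markers to fall, by 1.20 ± 0.19 (median -0.03, camera adjusted p = 0.862). Clu, clusterin, was the only one of 19 tubular injury genes to fall, by 1.23 ± 0.21 (median -0.17, camera adjusted p = 0.780). Pck1 was the only one of 18 proximal tubule markers to fall, and 1 rose and 1 fell when adjusted over the list alone (median -0.01, camera adjusted p = 0.957). Aqp4 rose by 1.12 ± 0.20 (adjusted p = 0.0251) among 9 principal cell markers (median 0.21, camera adjusted p = 0.152). Ddit4 was the only one of 18 unfolded protein and stress genes to fall, 3 when adjusted over the list alone (median -0.34, camera adjusted p = 0.0524). Of these members, Calb1, Mme, Clu and Aqp4 lost their call without any 1 of the 4 transgenic libraries, with adjusted p values up to 1 for Calb1, 0.356 for Mme, 0.373 for Clu and 0.275 for Aqp4. Egf lost it without G0APOL1 replicate 2 (adjusted p = 0.139), G2APOL1 replicate 1 (adjusted p = 0.452) or G2APOL1 replicate 2 (adjusted p = 0.253). The unfolded protein list passed, down, without G0APOL1 replicate 2 (adjusted p = 0.00358), and principal cell markers passed, up, without G0APOL1 replicate 1 (adjusted p = 0.0439).

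In the remaining lists no member passed in edgeR's quasi-likelihood test over all genes for G2APOL1 against G0APOL1; at an unadjusted p under 0.05 each had 0 to 5 members, DESeq2 called 0 or 1 in each and limma-voom 0 or 1. The endothelial markers had a median of 0.23 (camera adjusted p = 0.0962), the fibrosis and matrix genes -0.06 (camera adjusted p = 0.814), the interferon response -0.02 (camera adjusted p = 0.814), macrophage markers 0.03 (camera adjusted p = 0.957) and podocyte markers -0.04 (camera adjusted p = 0.780). For fibrosis, interferon and podocytes camera's direction was up and the mean above 0, at 0.02, 0.07 and 0.06, and for macrophages it was down with a mean of -0.06. Urothelium markers had a median of -0.24 and a mean of -0.26 while camera's direction was up (camera adjusted p = 0.814), and 2 rose when adjusted over the list alone. Haemoglobin Hba-a1 was at -0.99 ± 0.20 (adjusted p = 0.0523; a log2 ratio of -0.47 with its near-identical copy summed), and DESeq2 and limma-voom called 1 red cell marker each. The smooth muscle and mesangial list was at 0.32 (camera adjusted p = 0.181), vasoactive genes at 0.28 (camera adjusted p = 0.154) and sodium transport at -0.12 (camera adjusted p = 0.280). Medians were -0.16 for cholesterol synthesis (camera adjusted p = 0.957), -0.03 for fatty acid oxidation, with 2 lower when adjusted over the list alone (camera adjusted p = 0.557), 0.11 for endothelial activation (camera adjusted p = 0.292), -0.33 for NF-kB and cytokine genes (camera adjusted p = 0.152), -0.23 for red cells (camera adjusted p = 0.212) and -0.22, with a mean of 0.49, for inflammasome, STING and lytic death (camera adjusted p = 0.814). They were -0.03 for hypoxia, with a mean of 0.04 (camera adjusted p = 0.780), 0.01 for Nrf2 targets (camera adjusted p = 0.718), 0.05 for nuclear and -0.24 for mitochondrial respiratory chain genes (camera adjusted p = 0.780 and 0.0962), -0.03 for mitochondrial dynamics (camera adjusted p = 0.966) and -0.03 for proliferation (camera adjusted p = 0.957). Intercalated cell markers were at -0.30 (camera adjusted p = 0.244), lymphocyte markers at -0.07 with a mean of 0.57 (camera adjusted p = 0.814), and complement and acute phase genes at -0.19 with a mean of 0.86, 2 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.814). Adipocyte markers were at 2.57, or 1.88 with genes at 0 counts set to their bound (camera adjusted p = 0.0962), with camera's direction up; it was up without G2APOL1 replicate 1 (adjusted p = 3.1e-07) and down without G2APOL1 replicate 2 (adjusted p = 0.708) only. The cholesterol list passed in opposite directions, up without G0APOL1 replicate 1 (adjusted p = 0.0439) and down without G0APOL1 replicate 2 (adjusted p = 0.00358). Endothelial markers passed, up, without G0APOL1 replicate 1 (adjusted p = 0.0439), and the mitochondrial genome, down, without WT replicate 1 (adjusted p = 0.0321) or WT replicate 2 (adjusted p = 0.0411). Edn1 was at 2.47 ± 1.30 (adjusted p = 0.804), Nos3 at 0.53 ± 0.45 (adjusted p = 0.929), Ren1 at -0.58 ± 0.55 (adjusted p = 0.960), Lcn2 at 0.39 ± 0.63 (adjusted p = 0.979), Vcam1 at -0.74 ± 0.52 (adjusted p = 0.894), Havcr1 at -0.87 ± 1.16 (adjusted p = 0.972) and Tmem173 at -0.41 ± 0.99 (adjusted p = 0.987). Nlrp3 and Xist were below the filter on low counts.

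The largest rise was that of Serpina1d (ENSMUSG00000071177.4, chromosome 12, 103763594 to 103773592), with 3775 counts over G2APOL1 and 0 over G0APOL1, at least 1067-fold. With its 4 near-identical copies summed, the difference stood at 243 against 1.18 CPM. Its relative Serpina1a rose by 5.57 ± 0.44 (256 against 8.98 CPM with its 5 copies summed), Angptl7 by 2.68 ± 0.32, from 22.5 ± 10.5 to 144 ± 5.98 CPM, and Gfra1, a receptor of the growth factor GDNF, by 2.54 ± 0.33. The ribosomal protein gene Rpl29, with 3 near-identical copies, rose by 2.46 ± 0.20 (405 against 74.2 CPM with the copies summed), Nipal2 by 1.98 ± 0.34, Gstp3 by 1.95 ± 0.37, Clec2h by 1.80 ± 0.30, Ccdc6 by 1.73 ± 0.19 and the steroid dehydrogenase Hsd3b2 by 1.53 ± 0.20. Hist1h2al was at least 52.0-fold higher, but with its copies summed the values were 279 CPM in G2APOL1 and 354 in G0APOL1. Reep3 had 0 counts in G2APOL1 and was at least 530-fold lower, and Tpbgl at least 16.9-fold. Tmem267 fell by 2.56 ± 0.27, the receptor Lrp8 by 3.85 ± 0.73, Cyp24a1, which inactivates vitamin D, by 2.40 ± 0.40 and Lipo3 by 2.17 ± 0.36. Hyal1, which shares 50.8% of its exonic bases with Naa80, fell by 2.72 ± 0.50. Cyp4a31 fell by 2.46 ± 0.20 and Eif3j2 by 2.93 ± 0.35, with 2 and 1 near-identical copies. With the copies summed, Cyp4a31 stood at 345 against 743 CPM (log2 ratio -1.11), while Eif3j2 was not lower, at 59.7 against 57.0 CPM.

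Of the 24 genes with the largest changes, 11 kept their call whichever library was left out: Nr1d1, Serpina1d, Serpina1a, Angptl7, Rpl29, Ccdc6, Hist1h2al, Reep3, Tmem267, Cyp4a31 and Eif3j2. Lrp8 was at -3.23 (adjusted p = 0.34) without G2APOL1 replicate 2. The number of genes called was 150 without WT replicate 1, 141 without WT replicate 2, 30 without G0APOL1 replicate 2, 35 without G2APOL1 replicate 1 and 27 without G2APOL1 replicate 2, and 134 with DESeq2.

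Of the 69 genes called between the transgenic groups, 42 were also called in G2APOL1 against WT, 37 in G0APOL1 against WT and 2 in neither. Reep3 was high in G0APOL1 alone, at 75.4 ± 7.79 CPM against 0.149 ± 0.21 in WT. Cyp4a31 stood at 301.3 ± 15.9 CPM in G0APOL1 and 37.1 ± 6.52 in WT, but with its copies summed the difference was smaller, at 743 against 353 CPM (log2 ratio 1.07). Of the 736 genes called against WT in both transgenic groups in the same direction, 9 were called between them. A p value that misses the threshold does not show that the variants act alike at this number of libraries.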

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

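The alternatives were chosen before the data were examined, except those without genes that have a near-identical copy and with a WT library of its own for each comparison, which were chosen after seeing the data. With 2 libraries per group, a left-out library leaves a lone sample that is assumed to vary like the other groups, and at this depth and number of libraries the simulations recovered 15% to 26% of the genes changed 2-fold. For G2APOL1 against WT, 1178 genes became 1806 without the low-count filter and 338 to 1835 with a library left out (338 without G2APOL1 replicate 1, 1835 without WT replicate 1). For G2APOL1 against G0APOL1, 69 became 245 without the filter, 134 with DESeq2, 119 with only the 4 libraries compared, 120 with a replicate block and 27 to 150 with a library left out (27 without G2APOL1 replicate 2, 150 without WT replicate 1). For G0APOL1 against WT, 1175 became 658 with only the 4 libraries compared and 599 to 1721 with a library left out (599 without G0APOL1 replicate 1, 1721 without WT replicate 1). The overlap of 736 genes became 1113 without the filter, 456 with only the 4 libraries compared and 248 to 1231 with a library left out (248 without G2APOL1 replicate 1, 1231 without WT replicate 1), and 510 and 493 with a WT library of its own for each comparison. Fits without a filter test more genes and fits of 4 libraries use fewer samples. The main fit also shares 1 estimate of spread over the 3 groups, and the WT pair was the least alike (correlation of log2 CPM 0.913). WT spread therefore enters the test between the transgenic groups, so 69 is no like measure beside 1178 and 1175. With only the 4 libraries compared, G2APOL1 against WT had 1093. Giving each comparison a WT library of its own takes the spread from the transgenic pairs alone. Beyond that the cause was not tested. The remaining settings stayed within 1.5 times the counts given, with 1156, 68 and 1121 genes under DESeq2 size factors, 1254, 58 and 1101 with limma-voom, and 1157, 50 and 1135 without genes that have a copy, for G2APOL1 against WT, G2APOL1 against G0APOL1 and G0APOL1 against WT. DESeq2 gave no adjusted p for 4738, 5923 and 5133 genes.

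For gene lists, camera with an estimated correlation called 0, 0 and 0 in place of 15, 1 and 17 for the same comparisons, and fry called 8 for G2APOL1 against WT and 0 for G2APOL1 against G0APOL1. The latter comparison had 2 lists with a replicate block and 0 to 4 with a library left out, 0 without G2APOL1 replicate 2 and 4 without G0APOL1 replicate 1. The cause was not tested. The labels reuse replicate numbers 1 and 2 in each group. Across genes, which are not independent replicates, the deviations of replicates 1 and 2 from their group means correlated at 0.0956, 0.0578 and 0.0426 between pairs of groups. These values give little sign that the numbers pair the samples. A replicate block did raise the genes called, to 1724 in G2APOL1 against WT, 120 in G2APOL1 against G0APOL1 and 1618 in G0APOL1 against WT. Whether the numbers carry shared variation stays open. The planned fit with sex as a covariate was not run, because all 6 libraries express Y-linked genes (Ddx3y counts of 234 to 273).

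Of 222 values of named genes, with list members taken only from lists that passed, 184 were called. Of these, 57 lost the call under some setting with all libraries, 104 when some library was left out, and 0 changed direction while called in the fit of all libraries. With some library left out 35 of the 184, whether or not the call was kept, shrank by over 1.5-fold, such as Vcam1 from -2.13 to -1.43 in G2APOL1 against WT without WT replicate 2. Values outside that set shrank too. In G2APOL1 against WT, Sgk1 went from -1.93 to -1.30 without WT replicate 1 and Casp4 from -4.42 to -2.9 without WT replicate 2. Genes that were not called did change sign with a library left out, and the cause was not tested. Their ranges were -0.42 to 0.0371 for Ddx3y, without G2APOL1 replicate 2 and G2APOL1 replicate 1, and -0.81 to 0.21 for Havcr1, in G2APOL1 against WT. In G2APOL1 against G0APOL1 they were -1.27 to 0.22 for Vcam1, -0.32 to 2.06 for Lcn2 and -0.36 to 0.0900 for Ddx3y. In G0APOL1 against WT they were -0.61 to 0.15 for Tmem173 and -0.0832 to 0.00970 for Ddx3y.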

Other observations

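All tests weighed here were written down before their values were computed, but on patterns already seen in the data, and the lists of kidney zones, clock arms and steroid-responsive genes were written after the largest changes were seen. The added condition that the steroid result hold with each library left out came after its values were seen.

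Some clock genes differed between the groups. Of 17 circadian genes, 1 rose and 2 fell in G2APOL1 against WT, 2 rose and 3 fell in G0APOL1 against WT, and 2 rose in G2APOL1 against G0APOL1, with medians of 0.04, 0.35 and 0.08. The repressor Nr1d1 fell by 0.97 ± 0.20 in G2APOL1 and by 2.60 ± 0.21 in G0APOL1 against WT. Dbp, an output gene of the clock that shares 18.0% of its exonic bases with Sphk2, fell by 1.79 ± 0.22 in G0APOL1 against WT and rose by 1.38 ± 0.22 (adjusted p = 0.0138) in G2APOL1 against G0APOL1. Hlf rose by 0.95 ± 0.18 and 1.20 ± 0.18 against WT in G2APOL1 and G0APOL1. Between the transgenic groups, the 5 genes listed as the positive arm (Arntl, Npas2, Clock, Nfil3 and Cry1) had a median of -0.3926 (95% bootstrap interval over genes -1.26 to 1.01). The 8 listed as the negative arm (Nr1d1, Nr1d2, Dbp, Tef, Hlf, Per3, Ciart and Bhlhe41) had a median of 0.21 (-0.25 to 1.38). The test of another time of day at collection therefore decided nothing there. The arm names are list labels and do not say whether a gene activates or represses. Against WT, positive-arm medians were 1.41 (0.12 to 1.56) in G2APOL1 and 1.27 (0.43 to 2.68) in G0APOL1. Negative-arm medians were -0.27 (-0.97 to 0.16) and -0.58 (-2.0 to 0.39), with intervals that include 0. In WT, the positive-arm genes Arntl and Npas2 averaged 0.57 and 0.49 CPM. Another time of day against WT was not tested and stays open. With a library left out, Nr1d1 lost its call in G2APOL1 against WT without either G2APOL1 library, Hlf there without G2APOL1 replicate 2, and Dbp between the transgenic groups without G0APOL1 replicate 2 or G2APOL1 replicate 1.

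Of 8 genes known to be higher in male kidney, 3 rose in each transgenic group against WT, Cyp2e1 by 1.72 ± 0.24 in G2APOL1 and 1.35 ± 0.24 in G0APOL1, with medians of 0.80 and 0.59, and the median between the transgenic groups was 0.15. Of 4 genes known to be higher in female kidney, the prolactin receptor Prlr rose by 2.67 ± 0.62 and Cyp4a14 by 1.52 ± 0.38 in G0APOL1 against WT (medians 0.96 there, -0.22 in G2APOL1 against WT and -1.10 between the transgenic groups). The 4 Y-linked genes had medians of -0.24, -0.14 and -0.08 in G2APOL1 against WT, G2APOL1 against G0APOL1 and G0APOL1 against WT, with Ddx3y at -0.20 ± 0.26, -0.16 ± 0.26 and -0.04 ± 0.26, and Xist had 45 counts in WT replicate 1, 4 in G2APOL1 replicate 2 and 0 elsewhere. Of 16 immediate early genes, Ier3 rose by 0.94 ± 0.22 and Klf6 fell by 1.16 ± 0.28 in G0APOL1 against WT, and medians were -0.69, -0.24 and -0.33 in the order given for the Y-linked genes. Prlr, Cyp4a14, Ier3 and Klf6 lost their call without G0APOL1 replicate 1, among other libraries. The adipocyte transcripts Car3 and Cfd stood at 69.6 ± 94.7 and 52.8 ± 74.2 CPM (mean ± SD) in G2APOL1, carried by replicate 2.

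The first pattern weighed is the shared difference of both transgenic groups from WT. Podocyte markers, which mark cortex, had a median of -0.3274 in G2APOL1 against WT and of -0.463 in G0APOL1 against WT. Both lie below the rise above 0.5 that less cortex in the WT pieces would give. Proximal and distal convoluted tubule markers did rise above 0.5, with medians of 1.18 and 0.85 in G2APOL1 and 1.11 and 1.59 in G0APOL1. As these lists went different ways, the podocyte test alone does not settle whether the WT pieces held less cortex. Inner medulla genes, without those already seen, had a median of -1.3151 in G2APOL1 and -1.8125 in G0APOL1 against WT. More inner medulla and pelvis in the WT pieces is a candidate explanation for the tubule and urothelium part. It would also lower the share of cortex in WT, which the podocyte median did not show, while the tubule medians above went that way. The urea transporter Slc14a2 was down by 1.27 ± 0.26 (not called without either G2APOL1 library) and 1.84 ± 0.27, and Cryab by 1.70 ± 0.26 and 2.04 ± 0.26. Of the 9 inner medulla genes, 6 were called lower in each comparison against WT. In G2APOL1 against WT, Slc4a11, Cldn4, Krt7 and Fxyd5 too lost their call without 1 or both of the G2APOL1 libraries. Slc4a11 and Fxyd5 also lost it without WT replicate 2, and Cldn4 without WT replicate 1. Cryab kept its call there whichever library was left out. Slc5a3 and Akr1b3 were called in neither, and Slc6a6 was at 0.17 and 0.39. For these genes the unadjusted p was 4.49e-05 with camera, 0.0240 with an estimated correlation (0.0595 to 0.0959 with a library left out) and 0.000859 with fry in G2APOL1 against WT. The transgene itself, more injury in WT and a difference in genetic background stay open, since each is confounded with the groups. Another time of day at collection was not tested for this pattern and also stays open.

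The second pattern is the set of 345 genes called in some comparison with a change of over 2 log2 units. Neighbouring pairs among them numbered 9, against a mean of 6.74 and a highest of 19 in 1000 shuffles along the genome. Large changes thus lay side by side no more often than in the shuffles. The test counts only directly adjacent tested genes of different families, so it cannot see a segment with unchanged genes between its changed ones. It decides nothing on chromosome segments of another strain, nor on a difference spread over the whole background. Among all called genes the pairs numbered 98 in G0APOL1 against WT (mean 77.7, highest 104 in the shuffles) and 88 in G2APOL1 against WT (78.2 and 112). Between the transgenic groups there were 3 among the 69 (0.246 and 3). Of these, Hsd3b4 with Gm10681, its near-identical copy, and Gm10681 with Hsd3b2 lie within the Hsd3b family. Only Rpl29 with Acy1 joins different families. Segments are therefore excluded in none of the comparisons. A near-identical copy was present for 35 of the 345, 10.145% (95% interval 7.17 to 13.8) against 3.93% of all tested genes. Reads divided between such copies are thus argued against as the main source. Genes that overlap at the same place and shorter matches were not counted as copies. Reads divided among those are not covered, as for Ugt1a9, which shares 59.9% of its exonic bases with other Ugt1a genes. Among those 35, the counts summed over each gene and its copies differed by a median of 1.6614 (0.640 to 2.75), with 9 families under 0.5 and 22 over 1. For the 35 as a set the test could not tell divided reads from a true change, as families went both ways. Some families were nearly level, such as Rps3a3 at 437 against 502 CPM in G0APOL1 against WT. Others differed as a whole, such as Serpina1a at 256 against 8.98 CPM in G2APOL1 against G0APOL1.

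The third pattern is the lower level of Sgk1, Ddit4, Bcl6, Pck1 and Txnip in G2APOL1 than in G0APOL1, of which Txnip (-1.64 ± 0.27, adjusted p = 0.0171) was chosen after its value was seen. A lower glucocorticoid response may contribute, since 10 other responsive genes had a median of -0.8908, all 10 below 0; edgeR's test called 0 of them, limma-voom 0 and DESeq2 3, and 6 had an unadjusted p under 0.05. Without G0APOL1 replicate 2 the median of these 10 was -0.17, with 8 of 10 below 0, so that median rests on that library, and it lay between -0.82 and -1.15 without any other; the unadjusted p of the 10 was 0.000116 with camera, 0.21 with an estimated correlation and 0.155 with fry. Without it Sgk1 went from -1.94 to -1.92, Ddit4 from -1.93 to -1.36, Bcl6 from -2.42 to -1.57, Pck1 from -1.54 to -1.19 and Txnip from -1.64 to -1.17, all below 0 but no longer called. Against WT, the 10 genes had a median of -1.20 in G2APOL1 (95% bootstrap interval over genes -1.79 to -0.22, 8 below 0), and of -1.18 there without G0APOL1 replicate 2. Camera with an estimated correlation gave an unadjusted p of 0.337. Per1, Mt1 and Cebpd fell, but none was called without G2APOL1 replicate 2. Per1 and Mt1 also lost their call without G2APOL1 replicate 1, and Per1 without either WT library. In G0APOL1 against WT the median was 0.23, which became -1.08 without G0APOL1 replicate 2. Between the transgenic groups a lower response and 1 deviating library therefore cannot be told apart, and an effect of the risk variant stays open.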
